A study of Mus musculus with 33 samples.

How the data were processed

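RNA of RAW264.7 cells, a mouse macrophage-like line, was measured on 33 one-colour arrays in 11 groups of 3. The groups were vehicle (0.1% DMSO), lipopolysaccharide (LPS) at 1 µg/ml, and LPS with albiflorin, paeoniflorin or paeonol at 1, 10 or 100 µg/ml, all for 6 h. Per the labels' protocols the RNA was labelled with digoxigenin and read by chemiluminescence. The text on the series' design gives 3 biological replicates per treatment and an array that covers the mouse genome.

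The deposited scanner tables hold 33012 gene probes and 303 control spots. Their signal column is an intensity on a linear scale with no normalization between arrays, per the file headers and from the values. The deposited tables also give a signal-over-noise score and a quality flag for each spot. From the values, a probe whose signal lay below its standard deviation carries that standard deviation as its signal, which held for 37.6% to 45.4% of the gene probes of an array. The scanner software is not stated. The treatment codes and run ordinals in the file headers matched the labels on 33 of 33 arrays. A further deposited table holds the authors' processed log2 values. Its column for vehicle replicate 1 differed from the log2 scanner signal by at most 2.24e-06, and the other columns were shifted smoothly towards that array, with rank correlations of at least 0.993. Its column medians ran from 9.89 to 10.11. The authors' normalization method stays unknown, and this table was used as an alternative only.

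Spots with a quality flag above 5000 were set missing, control spots were left out, and the signals were quantile normalized between arrays. They were floored at the 5th percentile of the normalized values, which was 165.7, and taken to log2. A probe was tested if its signal over noise was at least 3 on 3 or more of the 33 arrays. This kept 19438 probes, of which 1785 had a missing value on some array. A probe below that detection limit on every array of a group has only a bound there. Its fold is then given as "at least", from the brighter group's mean and, in the dim group, the higher of the lowest detected signal and the probe's own on each array. Such a fold is a bound for detection only and takes no account of the error of the means. For a gene that was not called it does not show that the gene changed. The number of arrays limits the precision. The median standard error of a log2 difference between a pair of groups was 0.337 in most comparisons.

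Gene names were scarce. The files pair most probes with identifiers that the table of mouse RefSeq genes (assembly GRCm38.p6, used for names only) does not hold. Names were found for 317 of 33012 probes, covering 311 symbols. These were 311 of 517 probes with a RefSeq accession and 6 of 337 with one kind of GenBank accession. None of 27930 probes with a Celera gene identifier was named. Of the tested probes, 183 had a name. A probe without a name is unnamed here, which does not mean that it has no gene. The text names genes by a rule fixed before the data were examined. For LPS against vehicle these were the 15 risen and 10 fallen named genes with the largest change among those called, with groups that did not overlap and detection on all arrays of the higher group. For each compound at 100 µg/ml the numbers were 10 each way, at lower doses 3 each way, and for trends and matched doses 5 each way. Where none passed, the 3 named genes with the smallest p are given as values. Up to 4 members of each fixed list were added. Of 557 members of 21 lists fixed beforehand, 4 were named here (Tlr7, Nlrp3, Cebpb and Aldh3a1), and Aldh3a1 did not pass the detection filter. The tests of those lists, the planned score over 3 of them and the planned values of Tnf, Il1b, Il6, Nos2, Ptgs2, Ccl2, Cxcl10, Ifnb1, Hmox1, Il10 and Actb were therefore not run. For each main comparison up to 2 unnamed probes that rose and 2 that fell are given by their probe number.

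All 33 arrays entered one linear model with 11 group means in limma 3.58.1 (R 4.3.3), with lmFit and eBayes and 2-sided tests. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe was called at an adjusted p under 0.05. LPS was compared with vehicle and each compound group with LPS. Dose trends were slopes on log10 dose over the 9 arrays of a compound, in log2 per 10-fold dose. Compounds were compared at matched doses with limma's moderated F over the 3 doses and with single-dose contrasts.

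Per the file headers, arrays with one replicate number share a scan day, for 3 of 3 numbers, so the replicate number marks a shared day and was also fitted as a block. The median correlation of deviations from the group means was 0.192 for arrays of one day and -0.11 for arrays of different days. The deviations cancel out within a group, which ties the second value to the first. Every pair lay over 0.1 in 6 of 10 comparisons. The rest were paeonol at 1, 10 and 100 µg/ml and paeoniflorin at 100 µg/ml against LPS, with lowest values of -0.168, 0.0625, -0.00149 and -0.217. For these the pairing by day was not shown. The files give no slide number. Gene probes with a wide gap split the arrays: 36 probes set 18 arrays apart from the rest, and 8 probes set 10 apart. This gave 3 array batches of 15, 10 and 8. A manufacturing control spot parted only the batch of 10, with a signal of at most 591.67 there. Its ranges overlapped in the batch of 15 (68512.56 to 375835.67) and the batch of 8 (149253.5 to 293772.48). That division was made from the values after the data were examined. The batch of 10 held no paeonol array, and the batch of 8 held 6 paeonol arrays, 2 paeoniflorin arrays and neither vehicle nor LPS alone. One of these 2 paeoniflorin arrays was paeoniflorin 10 replicate 1, which stands apart from all other arrays. No model with the array batch as a block was run without it, so the values with that block rest partly on this array.

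Because the planned score was not possible, an LPS score was set up after the data were examined. For an array of one day it is the mean log2 difference from that day's vehicle array, signed by the direction of the LPS change, over the probes with an LPS change of at least 2-fold on the other days. The compounds were set against the LPS array of the same day with exact permutation tests that swapped labels within days and chose the probes again each time. These tests take no account of the array batch, so a linear model of the score with scan day and array batch, and an exact test of paeonol 100 against the other paeonol doses of its day and batch, were added after the results had been seen. The return of LPS-changed probes was measured over 2779 called probes without missing values, as the share whose compound difference opposed the LPS change and as the slope of one on the other. Because both differences use the LPS arrays, the values were set against 1000 simulated unchanged groups that shared the LPS arrays. The simulation first used the LPS change as measured. It was altered to shrink that change by its own error after the first form gave too low a return for simulated unchanged groups, and after the real values had been seen. Both forms are reported for the share, and only the altered form for the slope. The same simulation, on the 28 top probes of an unchanged group, gave what shared LPS arrays alone do to probes chosen for their difference from them, and what picking them gives against other groups.

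The tests were tested on simulated data with 200 of 19438 probes changed. For LPS against vehicle, 31% of 2-fold and 70% of 4-fold changes were recovered, with 1 false call. For paeonol 100 against LPS these were 30% and 71%, with 2 false calls. With 25% of the LPS change returned in a simulated paeonol 100 group, the slope found was -0.272. None of the simulated unchanged compound groups, 0 of 8, passed. The noise was drawn independently for each probe and array, with no scan day, array batch or correlation between probes. The false calls and the groups that passed may therefore be more on the real arrays.

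Alternatives chosen before the data were examined were median normalization, the authors' table, a floor at the 20th percentile, no detection filter, detection on at least 17 arrays, kept quality-flagged spots, a trended and robust variance, array weights, only the compared groups in the model, the replicate block, and each array left out. Chosen afterwards were the array batch as a block, alone and with the replicate block, and the model without paeoniflorin 10 replicate 1, alone and with the replicate block.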

Results

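The data are 33 arrays of RAW264.7 macrophage-like cells, 3 in each of 11 groups. The median signal of an array before normalization ran from 335.9 to 1439.7, and 38.2% to 49.7% of the gene probes were detected. The lowest detection and the lowest median correlation with the other arrays, 0.908, were those of paeoniflorin 10 replicate 1. Without it the lowest were 40.6% and 0.943. Paeonol 10 replicate 3 had the most quality-flagged gene probes, 2011 against a median of 239 per array. It was also the only array with gene probes of zero signal, 352 of them.

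The first comparison asks how the cells responded to LPS, a bacterial cell wall component that activates macrophages. LPS raised Ifi202b, an interferon-activated gene, 25.2-fold (log2 difference 4.65 ± 0.235 SE, n = 3 per group, limma adjusted p = 1.56e-13). It also raised Trim34a, a tripartite motif gene, 14.1-fold (3.82 ± 0.334), although Trim34a was detected on 1 of 3 vehicle arrays. Nlrp3, a sensor of the inflammasome, was 3.76-fold higher (1.91 ± 0.458, limma adjusted p = 0.00434), and Bcl2a1b, an anti-apoptotic Bcl-2 family member, 4.63-fold higher (2.21 ± 0.172). Nanos1, an RNA-binding protein gene, was at least 8.45-fold lower with LPS, where it was below the detection limit on all 3 arrays.

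Further named genes rose after LPS. Cebpb, a transcription factor of macrophages, rose 1.78-fold (0.83 ± 0.178), and Stat5a, a mediator of cytokine signalling, 2.48-fold (1.31 ± 0.435). The Cebpb values here are of probe 450590, and a second Cebpb probe, 640455, was not among the probes called higher. H2-Q7, a class I major histocompatibility gene, rose 1.51-fold (0.59 ± 0.162). Csprs rose by 4.31 ± 0.234 on the log2 scale. Shbg, which encodes sex hormone-binding globulin, was at least 14.4-fold higher and lay below the detection limit on all 3 vehicle arrays. C130026I21Rik rose by 2.74, Amigo3 by 2.11 (detected on 2 of 3 vehicle arrays), Wdfy1 by 1.53, Sowahc by 1.08, 2700081O15Rik by 0.90 and Smcr8 by 0.82. Of the pattern recognition receptors with a name here, Nlrp3 was called and Tlr7, a receptor for single-stranded RNA, was not (0.69 ± 0.418, limma adjusted p = 0.342). Cebpb was the only macrophage identity gene with a name here.

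**Figure D1:**
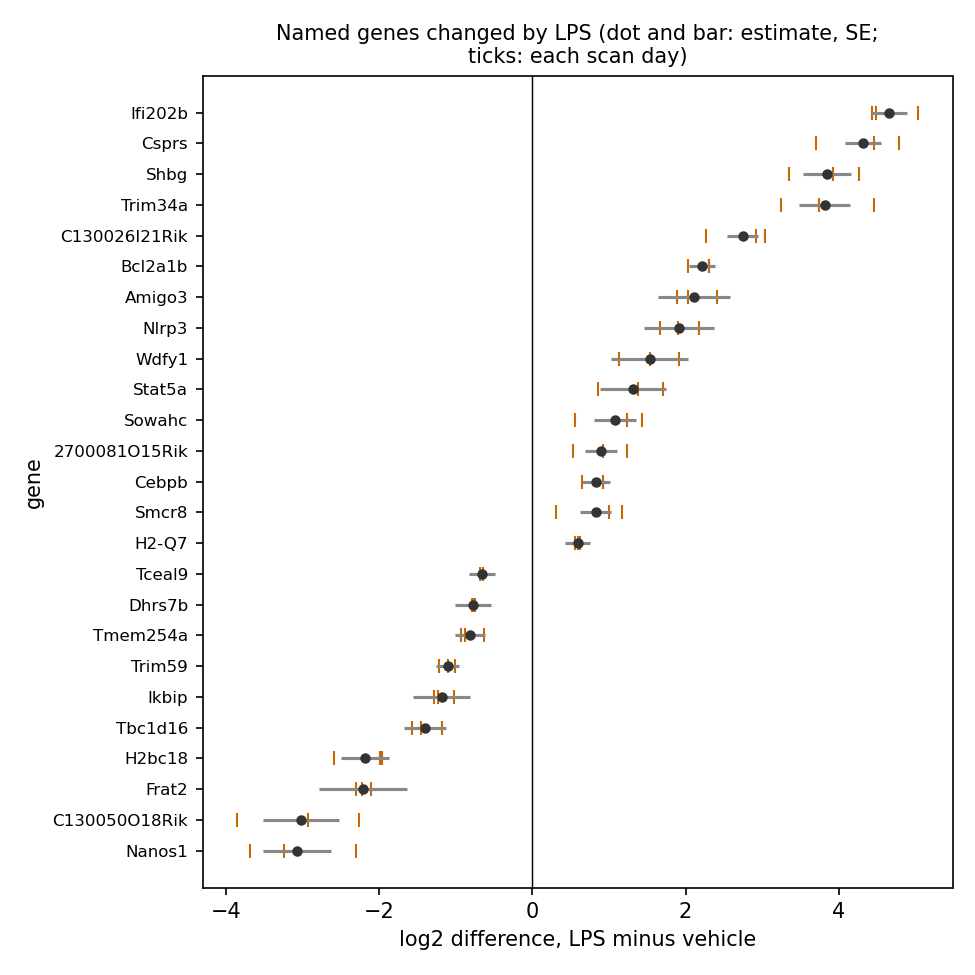
Log2 difference between LPS and vehicle (x axis) for the 25 named genes with the largest changes (y axis). Dots and bars are the estimates and standard errors, ticks are the differences on the 3 scan days. Ifi202b had the highest value, 4.65, and Nanos1 the lowest, -3.08, which is a bound, since Nanos1 lay below the detection limit with LPS.

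Among the genes that fell, H2bc18, a histone H2B gene, decreased by 2.18 ± 0.311 on the log2 scale and was detected on 1 of 3 LPS arrays. Frat2, which encodes an inhibitor of glycogen synthase kinase 3, was at least 4.54-fold lower and below the detection limit on all 3 LPS arrays. The log2 difference was -3.02 ± 0.497 for C130050O18Rik (detected on 2 of 3 LPS arrays), -1.40 for Tbc1d16, -1.18 for Ikbip, -1.11 for Trim59, -0.81 for Tmem254a, -0.77 for Dhrs7b and -0.66 for Tceal9.

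Over all probes, limma called 2905 of 19438, with 1280 higher and 1625 lower after LPS. The majority turned with median normalization (1016 higher, 865 lower) and with the authors' table (1512 higher, 1336 lower). The number at an unadjusted p under 0.05 was 4866, where chance gives 972. The largest changes were mostly increases: 195 probes rose and 9 fell at least 8-fold. Probe 734612 rose by 11.91 ± 0.345 and probe 888038 by 8.76 ± 0.491 on the log2 scale, while probe 907909 fell by 5.43 ± 0.612 and probe 553360 fell by 4.02 ± 0.895. Probe 734612 was detected on 1 of 3 vehicle arrays, and probes 907909 and 553360 on 1 of 3 LPS arrays each. None of these 4 has a name here. Of the 183 named probes tested, 16 rose and 18 fell. The median difference of the called probes in the direction of the call was 1.02 within the array batch of 15 (1 array per group) and 1.12 within the batch of 10 (2 per group), on arrays that also chose the probes. Of the 25 named genes, 13 kept their call under every alternative, and 12 lost it under some, mostly Stat5a (8 of 20 alternatives) and Wdfy1, Ikbip and Dhrs7b (6 of 20 each).

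The next comparisons ask what each compound changed in LPS-treated cells. Albiflorin, a monoterpene glycoside of peony root, had no named gene past the threshold at any dose. At 100 µg/ml the named genes with the smallest p were Eif4ebp1, a repressor of translation (log2 difference -1.02 ± 0.408, detected on 1 of 3 arrays and on 2 of 3 with LPS alone), Tnfsf13, a cytokine of the tumour necrosis factor family (-0.50 ± 0.215), and Ntn1, which was detected on 1 of 3 arrays and on 0 of 3 with LPS alone. All 3 had a limma adjusted p of 1. Nlrp3 differed from LPS alone by -0.27 ± 0.458 and Cebpb by 0.03 ± 0.178. At 1 µg/ml Nlrp3 had 0.03 ± 0.458, and the smallest p were those of genes below the detection limit on all 3 arrays of a group. These were Paqr9 (detected on 0 of 3 arrays and 1 of 3 LPS arrays), C130050O18Rik (at least 2.15-fold lower, detected on 2 of 3 LPS arrays) and Gpr27 (at least 1.90-fold higher, detected on 2 of 3 albiflorin arrays and 0 of 3 LPS arrays). At 10 µg/ml 9130023H24Rik had 0.53 ± 0.21 and Nlrp3 -0.18 ± 0.458. Paqr9 was detected on 0 of 3 arrays there too. Olfr993, detected on 2 of 3 arrays and on 0 of 3 with LPS alone, was at least 5.17-fold higher by the means. It was not called, and its SD among the albiflorin arrays was 1.73 on the log2 scale. Limma called 0 probes at each of the 3 doses, and 1 at 100 µg/ml with the replicate block (limma adjusted p = 0.0387), with median normalization and with the authors' table. At an unadjusted p under 0.05 there were 239, 403 and 361 probes at 1, 10 and 100 µg/ml, against 972 expected by chance. The 95% interval of the difference excluded a 2-fold change for 55.1% to 55.8% of the probes. Without albiflorin 10 replicate 1, 4 probes were called at 10 µg/ml, among them Olfr993 (limma adjusted p = 2.62e-05).

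Paeoniflorin, an isomer of albiflorin, also changed no gene past the threshold. At 100 µg/ml Nlrp3 differed from LPS alone by -0.36 ± 0.458 and Cebpb by 0.10 ± 0.178. The smallest p there were those of Olfr1126, below the detection limit on all arrays of both groups, Cdc42ep1 (at least 2.80-fold lower, detected on 0 of 3 arrays and 2 of 3 LPS arrays) and Gpr27 (at least 2.15-fold higher, detected on 2 of 3 arrays and 0 of 3 LPS arrays), each with a limma adjusted p of 1. At 10 µg/ml Coa3 had 0.35 ± 0.125, Jmjd4 -1.34 ± 0.424 and AY074887 1.67 ± 0.621 (limma adjusted p = 0.629), the last 2 detected on 2 of 3 arrays of each group, and Nlrp3 had -1.16 ± 0.458 with the same adjusted p. Without paeoniflorin 10 replicate 1, Jmjd4 had -0.53, AY074887 0.73 and Nlrp3 -0.67. At 1 µg/ml Nlrp3 had -0.19 ± 0.458. Cdc42ep1, detected on 0 of 3 arrays there, was at least 2.60-fold lower. Sox11 and Mapk1ip1l were each detected on 1 array at 1 µg/ml and on 0 of 3 with LPS alone. Limma called 0 probes at each dose, with 244, 1503 and 342 probes at an unadjusted p under 0.05 at 1, 10 and 100 µg/ml, against 972 expected by chance. The group at 10 µg/ml holds the array that stands apart from the rest.

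Paeonol, a phenolic ketone, lowered Shbg at 100 µg/ml. The level fell from 12.22 ± 0.61 (SD, n = 3) with LPS alone to 10.66 ± 0.553 on the log2 scale, a difference of -1.55 ± 0.311 SE (limma adjusted p = 0.0322), against 8.37 ± 0.148 in vehicle. The difference was -1.66, -1.45 and -1.54 on the 3 days. Nlrp3 differed from LPS alone by -0.65 ± 0.458 (limma adjusted p = 0.843), Tlr7 by -0.47 ± 0.418 and Cebpb by 0.25 ± 0.178, none of them called. Shbg was the only one of the 183 named probes that passed, and it lost its call under 8 of 20 alternatives. Over all 20 the log2 difference ran from -1.89 to -1.27 and the limma adjusted p from 0.000777 to 0.496.

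Limma called 28 probes for paeonol at 100 µg/ml, 7 higher and 21 lower than with LPS alone, of which 21 changed at least 2-fold. Probe 604718 rose by 1.82 ± 0.216 and probe 826918 by 1.52 ± 0.264, while probe 871811 fell by 2.63 ± 0.453 and probe 860577 fell by 2.62 ± 0.502, on the log2 scale. Probe 826918 was detected on 1 of 3 LPS arrays, and probes 871811 and 860577 on 1 and 2 of 3 paeonol arrays. Of the 28 probes, 24 were also called after LPS, where the 28 top probes of simulated unchanged groups held a median of 3 (95% range 0 to 11). At all 24 paeonol opposed the LPS change, and the shared LPS arrays alone gave a median of 100% opposed in the simulation. The median difference in the direction of the call was 1.44. It was 1.37 within the only array batch that holds both groups (1 array each, also among those that chose the probes). There the LPS array is of scan day 1 and the paeonol array of scan day 2. With the replicate block 94 probes were called, all 28 among them. With the array batch as a block 13 of the 28 stayed called. Median normalization, no detection filter and only the compared groups each called fewer probes than the main model, as given below. Leaving out 1 array moved the count to 8 without LPS replicate 2, 5 without LPS replicate 3, and 5, 9 and 53 without paeonol 100 replicates 1, 2 and 3.

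At the lower doses of paeonol no probe was called. The named genes with the smallest p at 10 µg/ml were Frat2, Mapk1ip1l and 9130023H24Rik. Frat2 was detected on 1 of 3 arrays and on 0 of 3 with LPS alone (limma adjusted p = 0.711). Mapk1ip1l lay below the detection limit on all arrays of both groups, and 9130023H24Rik (-0.68 ± 0.21) was detected on 1 of 3 arrays. At 1 µg/ml they were Coa3 (0.37 ± 0.125), Cops3 (-0.33 ± 0.113) and Rraga (0.48 ± 0.173). Limma gave 1293 and 584 probes at an unadjusted p under 0.05 at 1 and 10 µg/ml, against 972 expected by chance. The 28 probes called at 100 µg/ml had the same direction at 10 µg/ml in 28 cases, at 1 µg/ml in 27, at albiflorin 100 in 25 and at paeoniflorin 100 in 27. The shared LPS arrays alone gave a median of 28 (95% range 20 to 28) in simulated unchanged groups. Without paeonol 10 replicate 2, 3 probes were called at 10 µg/ml, among them Frat2 (limma adjusted p = 0.0233), whose difference rests on 1 array above the detection limit.

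**Figure D2:**
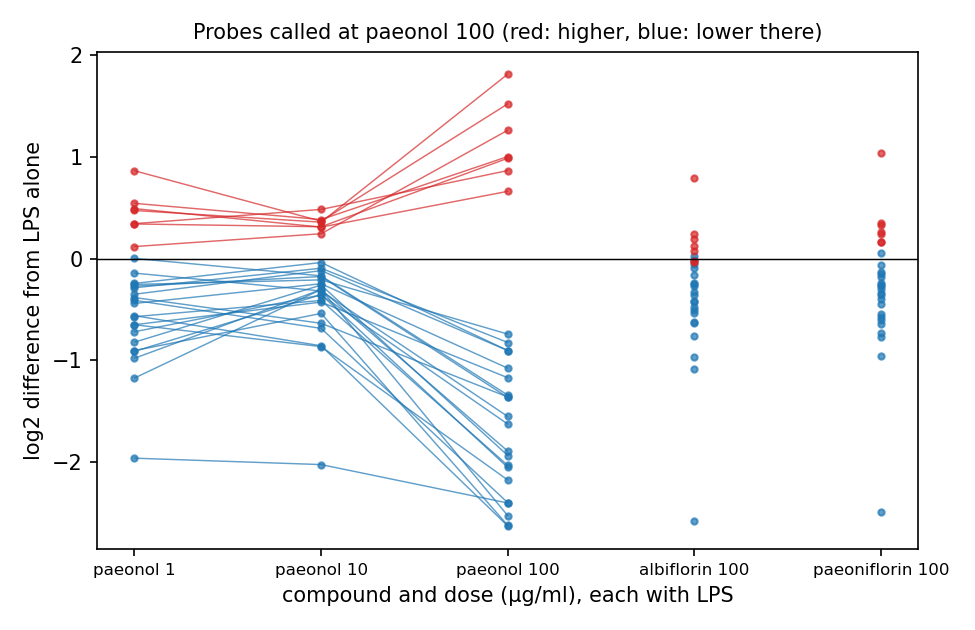
Log2 difference from LPS alone (y axis) of the 28 probes called at paeonol 100, at the 3 paeonol doses and at 100 µg/ml of albiflorin and paeoniflorin (x axis). Each point is 1 probe and lines join its values over the paeonol doses. The probes were chosen at paeonol 100, where their median difference in the direction of the call was 1.44.

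Dose trends ask whether a compound's effect grew with its dose, without use of the LPS arrays. Jun, a component of the AP-1 transcription factor, had a slope of -0.40 ± 0.0805 log2 per 10-fold dose of paeonol, from a level of 15.10 at 1 µg/ml to 14.31 at 100 µg/ml (limma adjusted p = 0.134). Shbg had a slope of -0.71 ± 0.164 (limma adjusted p = 0.225). With the replicate block Jun (limma adjusted p = 0.0304) and Shbg (0.0209) both passed the threshold. Hsd17b10 had a slope of 0.19 ± 0.071. Limma called 2 probes for the paeonol trend, 1 in each direction and neither with a name here, and 16 with the replicate block. Without any 1 of the 3 arrays of paeonol 100 the trend called 0 probes. For albiflorin and paeoniflorin limma called 0 probes, with 661 and 282 at an unadjusted p under 0.05, against 972 expected by chance. The named genes with the smallest p were Elf4 (-0.26 ± 0.109), Aldh3a2 (0.20 ± 0.09) and Fgf21 for albiflorin, and C130050O18Rik (0.46 ± 0.245), Tex46 and Fxr2 for paeoniflorin. Fgf21 was detected on 0 of 3 arrays at 1 µg/ml and 1 of 3 at 100 µg/ml. Tex46 (0 of 3 and 2 of 3) was at least 2.29-fold higher at 100 µg/ml than at 1 µg/ml, and Fxr2 (2 of 3 and 0 of 3) at least 2.63-fold lower.

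The compounds were then set against each other at matched doses. Albiflorin and paeoniflorin, which are isomers, differed at no probe past the threshold, over the 3 doses or at any dose. At 100 µg/ml Nanos1, below the detection limit on all 3 albiflorin arrays, was at least 2.70-fold lower with albiflorin, and Eif4ebp1, detected on 1 of 3 arrays of each group, had -1.29 ± 0.408. At 10 µg/ml Olfr993, detected on 2 of 3 albiflorin and 0 of 3 paeoniflorin arrays, was at least 5.84-fold higher. None was called (limma adjusted p = 0.972 over the 3 doses). At 10 µg/ml 4 probes were called without albiflorin 10 replicate 1, 8 without paeoniflorin 10 replicate 2, 1 without its replicate 3 and 0 without its replicate 1, the array that stands apart. Over the 3 doses 492 probes had an unadjusted p under 0.05, against 972 expected by chance. At 1, 10 and 100 µg/ml the 95% interval of their difference excluded a 2-fold change for 55.1%, 50% and 52.7% of the probes, so smaller differences between the isomers, and larger ones at the other probes, were not excluded.

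Paeonol differed from albiflorin at 3 probes over the 3 doses, all unnamed, at 2 probes at 1 µg/ml and at 6 probes at 100 µg/ml. It differed from paeoniflorin at 1 probe over the 3 doses and at 3 probes at 100 µg/ml. No probe was called at 10 µg/ml for either pair, or at 1 µg/ml for paeoniflorin, where limma gave 633, 1442 and 972 probes at an unadjusted p under 0.05. Of the named genes, Shbg was higher with paeoniflorin than with paeonol at 100 µg/ml by 1.61 ± 0.311 (limma adjusted p = 0.0800, and 0.597 over the 3 doses), and Jun by 0.57 ± 0.159 (limma adjusted p = 0.618). With the replicate block Shbg passed over the 3 doses (limma adjusted p = 0.0184) and at 100 µg/ml (0.00132). Between albiflorin and paeonol, 9130023H24Rik differed at 10 µg/ml by 1.22 ± 0.21 (detected on 1 of 3 paeonol arrays), Nupr1l at 100 µg/ml by -1.06 ± 0.258 and Nanos1 at 100 µg/ml by at least 3.83-fold, with 0 of 3 albiflorin arrays above the detection limit. None of these 3 was called, and with the replicate block 9130023H24Rik passed over the 3 doses (limma adjusted p = 0.0479). With the replicate block the 3-dose counts were 57 for albiflorin and 5 for paeoniflorin, and with the array batch as a block they were 0 and 0. At single doses the replicate block gave 16 calls at 1 µg/ml and 45 at 100 µg/ml for albiflorin and 17 at 100 µg/ml for paeoniflorin, and 1 array left out gave 0 to 2, 1 to 15 and 0 to 10.

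A last comparison asks how far each compound moved the cells back along the LPS response, with the LPS score set up after the data were examined. LPS alone had a score of 1.78 ± 0.159 (SD, n = 3). At 1, 10 and 100 µg/ml, albiflorin had 106%, 97.8% and 100% of that score, paeoniflorin 98.3%, 88.2% and 91.6%, and paeonol 89.9%, 96.6% and 77.5%. The mean difference from the LPS array of the same day was 0.027 ± 0.103 (SD over 3 days) for albiflorin (exact permutation p = 0.781), -0.127 ± 0.0971 for paeoniflorin (exact p = 0.125) and -0.211 ± 0.113 for paeonol (exact p = 0.0156, the smallest the 64 arrangements allow). After adjustment over the 3 compounds these p-values were 0.781, 0.188 and 0.0468. With paeonol 9 of 9 arrays lay below the LPS array of their day, with paeoniflorin 8 of 9 and with albiflorin 5 of 9. For a single dose the exact test allows no p under 0.125, which paeonol 10 and paeonol 100 reached. No paeonol array (0 of 9) is in the array batch of the LPS array of its day, against 7 of 9 for albiflorin and 4 of 9 for paeoniflorin, so the exact test does not part paeonol from the array batch. A linear model over 30 arrays gave paeonol -0.211 ± 0.108 SE with the scan day (adjusted p = 0.185) and -0.269 ± 0.142 with the array batch too (0.215). The paeonol doses share 1 batch on each day, and there paeonol 100 had the lowest score on 3 of 3 days, by -0.277 on average (exact permutation p = 0.0370, the smallest the 27 arrangements allow). That test was added after paeonol 100 had been seen to have the lowest score. Its arrangements take the dose as fixed beforehand, so this p is too small by an amount not computed. With day 1, 2 or 3 left out and the probes kept, the difference was -0.244, -0.146 and -0.245 for paeonol and -0.156, -0.0714 and -0.155 for paeoniflorin, and with detection on 17 arrays the adjusted p for paeonol was 0.141.

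**Figure D3:**
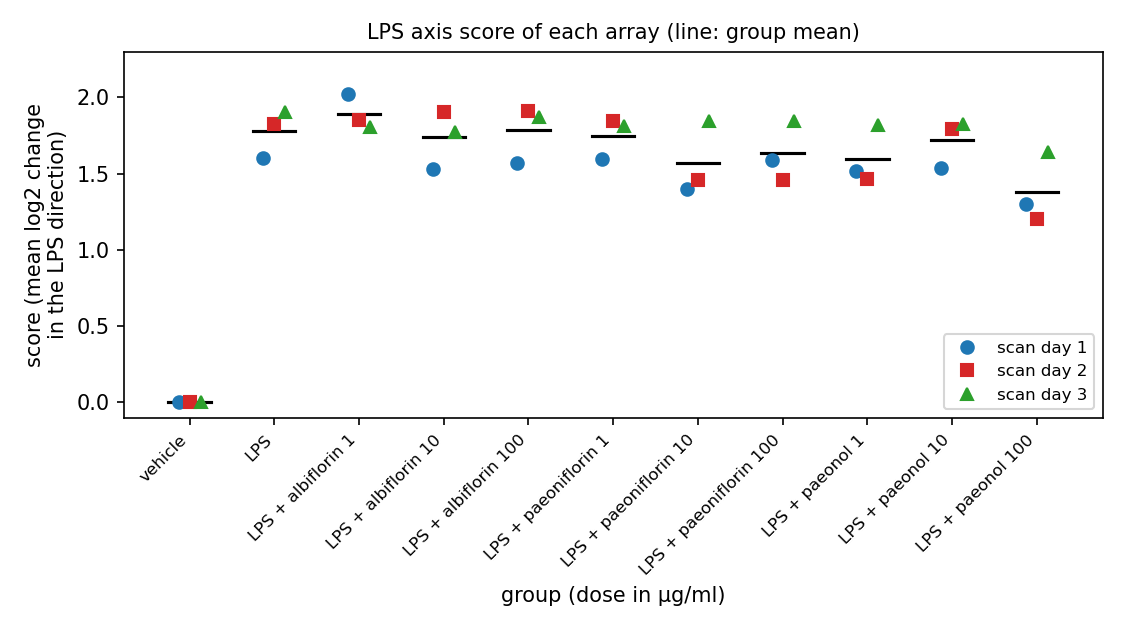
LPS score (y axis, mean log2 change in the LPS direction relative to the vehicle array of the day) of each of the 33 arrays by group (x axis), with lines at the group means and one symbol per scan day. LPS alone averaged 1.78 and paeonol 100 averaged 1.38.

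Over the 2779 LPS-changed probes, paeonol 100 opposed the LPS change at 85.4%, where simulated unchanged groups gave a median of 58.5% and a 95% range of 32.4% to 81.7% (adjusted p = 0.207 over the 9 compound groups, from the simulation). In the first form of the simulation, with the LPS change not shrunk, the adjusted p of this share lay under 0.05, as given below. The slope of the paeonol 100 difference on the LPS change was -0.224, against a simulated range of -0.139 to 0.0588 (adjusted p = 0.0180, from the simulation). The other 8 compound groups lay within the simulated range of both measures, with slopes between -0.118 at paeoniflorin 10 and 0.0357 at albiflorin 1. Within the 3 days the slope of paeonol 100 was -0.161, -0.349 and -0.162, and no simulated range was made for a single day. On day 2 paeonol 1, paeoniflorin 10 and paeoniflorin 100 had -0.213, -0.204 and -0.203, and the remaining groups lay between -0.0395 and -0.00402. On day 3 the slope was negative in every compound group. The differences of the compounds at 100 µg/ml from LPS correlated across probes at 0.439 for albiflorin and paeoniflorin, 0.366 for albiflorin and paeonol and 0.564 for paeoniflorin and paeonol. The shared LPS arrays alone gave a median of 0.504 and a 95% range of 0.0257 to 0.803. The covariances, 0.0601, 0.0599 and 0.0944, also lay within the simulated range of 0.00435 to 0.224. Probes are not independent replicates.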

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

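The comparisons below differed between compounds at the same dose by limma's test of the difference itself. The array batch values, the comparisons of paeonol 100 with other compound groups and the count over days were chosen after the results had been seen.

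Paeonol and albiflorin differed over the 3 doses at 3 probes, each lower with albiflorin at the dose with the largest difference. Between 100 drawn splits of their arrays within doses, 4 gave as many as 3 calls, the real one included, and the highest other split gave 3. The share among the other splits was 3.03%, with an exact binomial interval of 0.629% to 8.6%, and an earlier draw that could repeat a split gave 5 of 100, so the evidence against chance lies at the limit of 0.05. With the array batch as a block 0 probes were called. Paeonol and paeoniflorin differed over the 3 doses at 1 probe. Among 100 splits, 24 gave as many and the highest other split gave 24 calls, so chance cannot be excluded there. The splits of both pairs took no account of the scan day and were fitted without the replicate block. With that block the real groups gave 57 calls for albiflorin and 5 for paeoniflorin, for which no splits were drawn.

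Paeonol and albiflorin differed at 1 µg/ml at 2 probes, of which 1 was still called with the array batch as a block and 0 with the array batch and the replicate block together, while the replicate block alone called 16. They differed at 100 µg/ml at 6 probes, of which 3 were still called with the array batch and 6 with both blocks. Paeonol and paeoniflorin differed at 100 µg/ml at 3 probes, and these 3 were called in the same ways. Within the batch of 15, the only array batch that holds both groups for albiflorin, the median difference in the direction of the call was 1.05 and 1.54 on the log2 scale. For paeoniflorin it was 1.14 within the batch of 15 and 1.12 within the batch of 8. These values rest on 1 or 2 arrays per group, which also chose the probes and were not matched by scan day, and so decide nothing about the batch. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. In each of these 3 comparisons 1 of the 10 splits, the real one, gave as many calls, and the highest other split gave 1, 1 and 0.

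At paeonol 100 limma called 28 probes against LPS, and as the whole source of these the array batch, which differs between most paeonol and LPS arrays, is argued against by paeonol 1, whose arrays have the same batches and days: 26 of the 28 probes differed in the same direction between the paeonol doses at an unadjusted p under 0.05, where the 28 top probes of simulated unchanged groups, picked in the same way, gave a median of 6 and at most 18 in the 95% range, although the median size, 0.95 on the log2 scale, lay within what picking alone gave (0.13 to 1.14) and limma called 4 probes of all those tested between these doses. As the whole source of the calls, LPS arrays out of line by chance are argued against by the mean of the other 8 compound groups. From that mean 26 of the 28 differed at an adjusted p under 0.05 (simulated range 0 to 0), with a median of 1.22 (simulated range 0.31 to 1.07). Against LPS the median was 1.44, so a part played by the LPS arrays stays open. That 28 of 28 probes had one direction on all 3 days decides nothing about the scan day, since each group has 1 array per day and the same arrays chose the probes. With the array batch as a block 13 of the 28 stayed called. The median difference of the 28 was 1.43 ± 0.73 (SD) against 1.44 ± 0.62, and the median standard error was 0.278 against 0.246. The probes that lost their call were not examined apart, so why they lost it stays open, as does a part played by the batch. That paeonol at 100 µg/ml opposes part of the LPS response at the 28 probes is a hypothesis the design allows and was not tested independently.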

How the results depend on the processing

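The array batch, the model without paeoniflorin 10 replicate 1 and every setting of the LPS score were chosen after the data were examined. Every result of a comparison not named here kept its direction and its side of the threshold, or a count within 1.5 times, under each alternative run. The cause of the changes was not tested, except that only the compared groups leave few degrees of freedom.

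LPS against vehicle called 2905 probes (44.1% higher), 1881 with median normalization (1016 higher and 865 lower, 54% higher), 1766 with only the compared groups, 4467 with array weights, 4487 with the replicate block without the outlying array, 3774 with the replicate block, and 2053 to 2666 with 1 array left out. Paeonol 100 against LPS called 28 probes: 9 with median normalization, 12 with no detection filter, 0 with only the compared groups (1707 at an unadjusted p under 0.05), 213 with array weights, 94 with the replicate block, 207 with replicate and array batch blocks, 183 with the replicate block without the outlying array, and 5 to 53 with 1 array left out.

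The paeonol trend called 2 probes: 0 with median normalization, no detection filter or only the compared groups, 4 with detection on 17 arrays, 23 with array weights, 16 with the replicate block, 5 with the array batch, 23 with both blocks, 49 with the replicate block without the outlying array, and 0 to 4 with 1 array left out. Albiflorin against paeonol at matched doses called 3: 1 with median normalization, 8 with detection on 17 arrays, 1055 with array weights, 57 with the replicate block, 0 with the array batch, 281 with the replicate block without the outlying array, and 2 to 12 with 1 array left out (12 without paeonol 10 replicate 2). Paeoniflorin against paeonol called 1: 0 with median normalization, no detection filter, only the compared groups or the array batch, 50 with array weights, 5 with the replicate block, 5 with both blocks, 5 with the replicate block without the outlying array, and 0 to 3 with 1 array left out.

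Of the comparisons with 0 calls, 1 probe was called for albiflorin 1, paeoniflorin 1 and paeoniflorin 100 with array weights, and for albiflorin 100 with median normalization, the authors' table and the replicate block. With 1 array left out the counts ran from 0 to 2 for albiflorin 1, 0 to 4 for albiflorin 10, 0 to 1 for albiflorin 100, 0 to 1 for paeoniflorin 1, 0 to 2 for paeoniflorin 10, 0 to 1 for paeoniflorin 100, 0 to 2 for paeonol 1, 0 to 3 for paeonol 10, 0 to 1 for the albiflorin trend and 0 to 1 for albiflorin against paeoniflorin. At single matched doses, albiflorin against paeonol at 1 µg/ml called 2: 16 with the replicate block, 1 with the array batch, 379 with the replicate block without the outlying array, 2518 with array weights, 0 to 2 with 1 array left out, and 0 with both blocks and with median normalization, the authors' table, no detection filter, kept quality-flagged spots, only the compared groups or a trended and robust variance. At 100 µg/ml it called 6: 1 with median normalization, 0 with only the compared groups, 45 with the replicate block, 10 with the array batch, 112 with both, 100 with the replicate block without the outlying array, and 1 to 15 with 1 array left out. Paeoniflorin against paeonol at 100 µg/ml called 3: 0 with median normalization or only the compared groups, 9 with detection on 17 arrays, 163 with array weights, 17 with the replicate block, 14 with the array batch, 31 with both, 8 without the outlying array, 35 with the replicate block as well, and 0 to 10 with 1 array left out. At doses with 0 calls, array weights gave 1 for albiflorin against paeoniflorin at 1 µg/ml and against paeonol at 10 µg/ml, and 1 array left out gave at 10 µg/ml up to 8 for albiflorin against paeoniflorin, 4 for albiflorin against paeonol and 6 for paeoniflorin against paeonol. The replicate block changed no other count of calls named in the report by more than 1.5 times, and of the named genes only the calls of Jun and Shbg in the paeonol trend, of Shbg between paeoniflorin and paeonol and of 9130023H24Rik between albiflorin and paeonol. The scan day is the replicate number, so a scan day block is the replicate block.

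The LPS score difference of albiflorin was 0.027, -0.00431 with the authors' table and -0.0039 to 0.0768 with 1 day left out. The probes are then chosen on a single other day, which lowers the LPS score from 1.78 to between 1.09 and 1.11, so these values are on another scale. The paeonol difference was -0.211, -0.232 with detection on 17 arrays (adjusted exact permutation p = 0.141), and -0.155 to -0.0928 with 1 day left out, which is -14.0% to -8.50% of that LPS score against -11.9% for the 3 days, and fewer days allow no adjusted p under 0.05. With scan day and array batch in a linear model the differences were 0.0176, -0.156 and -0.269 for albiflorin, paeoniflorin and paeonol (adjusted p = 0.879, 0.318 and 0.215 over 30 arrays). For paeoniflorin 1 day left out gave -0.1 to -0.043, or -9.05% to -3.93% against -7.17%. The return share of paeonol 100, 85.4%, had an adjusted p of 0.027 with the LPS change not shrunk in the simulation, against 0.207, and ran from 81.3% to 89.1% with 1 array left out. Its adjusted p was 0.0448, the lowest that 200 simulations allow, without vehicle replicate 1 and without paeonol 100 replicates 1 and 3. It was 0.845 without LPS replicate 1 and 0.526 without paeonol 100 replicate 2. These labels were first set on unadjusted p, and moved to the adjusted p after they had been seen. On the unadjusted scale the paeonol 100 share lost its p under 0.05 in those last 2 settings, while albiflorin 1 without replicate 3 (32.3%) and paeoniflorin 10 without replicate 1 (75.8%) came under 0.05.

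Of 26 named genes called, 339 of 362 values kept the call and 23 lost it, with 26 of 156 lost when 1 array was left out, and none turned its direction. Of 88 named values that were not called, 18 of 1188 passed in some alternative and 20 turned direction without a call, and of 798 with 1 array left out 3 passed and 40 turned. Not run were the planned list tests and score with their alternatives, since too few members had a name, and a slide block, which the files do not give.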

Other observations

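The tests of this part were chosen after the results had been seen, except the slopes split by the direction of the LPS change and the splits of the arrays.

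The LPS response over the LPS-changed probes may have been partly reversed at paeonol 100. The slopes were not run without the probes called at paeonol 100, so a return beyond those was not tested. The return slope of paeonol 100, -0.224, uses the LPS arrays on both sides, and with paeonol 1 in their place on the compound side it was -0.112, outside the simulated range of -0.096 to 0.0965. Over the 1556 probes that LPS lowered, the slope of paeonol 100 against LPS was -0.259 (simulated range -0.211 to 0.0549), and over the 1223 that it raised it was -0.212 (-0.119 to 0.0707). The split against paeonol 1, without the LPS arrays on the compound side, gave -0.11 over the raised probes (-0.0929 to 0.0943) and -0.119 over the lowered ones, at the limit of its range of -0.118 to 0.123 and with a 2-sided simulation p over 0.05, so for the lowered probes the return is open. The score of paeonol and the slope share the vehicle and LPS arrays, so they are not independent.

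Paeoniflorin 10 replicate 1 had a median correlation of 0.908 with the other arrays. Its highest correlation with an array of another group was 0.923, below the 0.972 that every other array reached with its closest array. An array that stands apart from all others falls below that value whatever sample it carries. A sample of another group in its place is therefore not excluded. Low brightness is argued against by the 4 dimmer arrays, whose lowest median correlation was 0.962. What set the array apart stays open, and no biological explanation was tested.

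The 6 comparisons of albiflorin and paeoniflorin with LPS gave 239, 403, 361, 244, 1503 and 342 probes at an unadjusted p under 0.05, mostly fewer than the 972 of chance. A candidate explanation was that the outlying array and the scan day widen the spread all groups share. Without that array and with the day in the model, 1 of the 6 comparisons reached the number of chance, which argues against these as the whole source. Array weights gave 1739, 558, 569, 511, 706 and 1471, of which 2 of 6 reached the number of chance, so what lowers the numbers stays open.

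LPS against vehicle gave 2905 calls and the highest other of its 10 splits gave 0, with 1 split as large. Paeonol 100 against LPS gave 28, the highest other split 0, and 1 split was as large. For these, 10 splits are too few for a share under 0.05, and so they are for the single-dose comparisons with 0 calls, where 10 of 10 splits gave as many. The highest other split of those gave at most 2 calls, except for paeoniflorin against paeonol at 10 µg/ml, where a split that put the 3 arrays of the batch of 8 together gave 14. Among splits that part all 3 day pairs, none of that comparison gave a call.

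Of 100 drawn splits of the paeonol doses, 4 gave as many as the 2 calls of the trend, the highest other giving 7. The drawn splits took no account of the scan day and were fitted without the replicate block. The share among the other splits was 3.03%, with an exact binomial interval of 0.629% to 8.6%, and an earlier draw that could repeat a split gave 5 of 100, so the evidence against chance lies at the limit of 0.05. For the trends of albiflorin and paeoniflorin and for albiflorin against paeoniflorin, 100 of 100 splits gave at least the 0 calls of the real groups, with the highest at 630, 2 and 6. The 630 calls came from a split that put together as 1 dose 3 albiflorin arrays of the batch of 15, with the 2 dimmest arrays of all, albiflorin 10 and 100 replicate 2 (median signals 358.5 and 335.9), among them, which points to a structure of the samples other than dose.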
